A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

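The series measured polyadenylated RNA of budding yeast before and 15 min after addition of 0.4 M NaCl. Per the labels' protocols, wild-type (WT) BY4741 cells and a strain with HOG1 replaced by a KAN cassette (HOG1-KO) were grown in YPD to exponential phase. The 18 libraries form 6 groups of 3 biological replicates. Experiment 1 holds WT basal and WT salt libraries made with a stranded TruSeq kit, and experiment 2 holds WT and HOG1-KO basal and salt libraries made with the Lexogen CORALL kit. Reads were single-end and 50 bp long, per the labels' protocols.

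The authors deposited 2 tables of raw counts per gene, 1 for each experiment, with the same 7126 gene identifiers. Per the submitters' processing notes, HISAT2 version 2.1.0, featureCounts version 1.5.1 and the R64 genome build were used. The annotation release, the strand setting of the counting and the rule for reads that map to several genes are not given in the sources used here. Values of overlapping or antisense genes and of near-identical paralogs, such as ribosomal protein pairs, histone pairs and hexose transporters, are therefore uncertain to that extent. Every table column matched 1 sample by name, and 0 columns were left unmapped. In the reference annotation used here for names, 6048 identifiers were found, and 5988 of these had sequence features.

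Total counts per library ranged from 11135883 to 16527859. Counts in replicate pairs differed by more than sampling noise in every group (chi-square per degree of freedom between 6.53 and 174), so no library was treated as a repeat of another. Intervals and floors based on counts cover counting error only, since the counted reads are not known to be independent molecules. A group at 0 counts was compared through a floor of 3 counts over the group.

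The counts were tested with edgeR (version 4.0.16) in R (version 4.3.3). Library sizes were scaled by TMM factors, genes were kept by filterByExpr on the groups, and a robust quasi-likelihood F test was applied to contrasts of group means. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are described as called, higher or lower. Experiment 1 was fitted on its 6 libraries and experiment 2 on its 12 libraries, which share 1 estimate of the spread. The number of contrasts was 7, and the difference between the WT responses of the experiments was fitted on the 12 WT libraries. The design, the contrasts, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule for named genes took, per contrast, the 10 largest changes each way among called genes with a mean log2 CPM of at least 3 whose groups did not overlap (no such condition for differences of responses), up to 4 of the largest called changes in each gene list, HOG1 with its neighbours, and a panel of 19 genes. Dubious or unnamed features were skipped among the 10. Levels are TMM-scaled CPM, computed from the deposited counts and scaled within each experiment, as mean ± SD of 3 libraries. HOG1 and the auxotrophic markers are given as CPM of total counts. Fold changes are log2 values ± standard error.

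Gene lists, 39 in number and covering 966 genes, were written from textbook knowledge, and some genes stand in several lists. Of their symbols, 4 were not matched to an identifier, and the list of mitochondrially encoded genes had 0 tested members. Each list was counted with p-values adjusted over all genes and again adjusted over the list alone. Lists with at least 3 tested members were tested with camera in limma (version 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera was repeated with an estimated correlation, and fry, which does not compare a list with other genes, was run as another test.

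Upstream sequences of 500 bp were searched on both strands for the stress response element STRE (AGGGG), the PAC core (GATGAG) and the RRPE core (AAAATTT), and 200 bp were searched for the TATA form TATAWAW. Shares were compared with Fisher's exact test and medians with a permutation test of 100000 resamples, whose smallest p is 1e-05. The 27 tests were adjusted together. Intervals at 95% for medians came from 2000 bootstrap resamples. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

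Alternatives were DESeq2 (version 1.42.0), its size factor scaling (RLE), scaling by total counts alone, no low-count filter, a filter of at least 10 CPM in 3 libraries, a test against 1.5-fold (glmTreat), only the libraries compared, a replicate block, and leaving out each library in turn. After the data were seen, a fit without 2 deviating WT libraries of experiment 2 and offsets for coding GC and length were added, as were counts thinned at random to 50% in every library. In HOG1-KO, the deviations of each basal library from the group mean correlated best with those of the salt library of its number. The values were 0.16, 0.33 and 0.18 for numbers 1, 2 and 3. This did not hold for every library in the other comparisons. Some unlike numbers correlated more, such as basal 3 and salt 1 of experiment 1 at 0.485, so pairing is not established.

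The test was checked on simulated counts with 200 changed genes. The data called larger shares of genes for the salt responses, 69.2% in experiment 1, 57.2% in experiment 2 WT and 54.3% in HOG1-KO. Recovery and false calls depend on that share, so the values below describe the simulated setting and may differ for the data. For the salt response of experiment 1, 95.8% of 2-fold changes were recovered among 5877 genes. For the experiment 2 WT response, 75.4% were recovered among 6103 genes, and for the HOG1-KO response 72.4% among 6099. For the difference between the strains' responses, 4.8% of 1.5-fold, 40.9% of 2-fold and 93% of 4-fold changes were recovered among 6100 genes. For the basal strain difference 21.3% of 1.5-fold and 81.8% of 2-fold changes were recovered among 6103 genes, and for the difference between experiments it was 45.5% among 6082. Genes not changed in the simulation made up 7.61% of the calls for experiment 1, 4.65% for WT and 6.02% for HOG1-KO in experiment 2, 1.03% for the difference between responses, 4.17% for basal cells and 2.20% for the difference between experiments, where the threshold aims at 5%.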

Results

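RNA was counted in 18 libraries from budding yeast in exponential growth, before and 15 min after addition of 0.4 M NaCl. Experiment 1 compared basal and salt-treated wild-type (WT) cells. Experiment 2 compared basal and salt-treated cells of WT and of a strain lacking HOG1 (HOG1-KO), the stress-activated kinase of the high osmolarity glycerol pathway. Each of the 6 groups had 3 biological replicates, and totals ranged from 11135883 to 16527859 counts per library.

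HOG1 (YLR113W), on chromosome XII of R64 from 371620 to 372927, lies between YLR112W and AVL9. In WT cells its transcript stood at 358 ± 5.96 CPM (SD, n = 3) basal and 483 ± 7.42 CPM in salt in experiment 1, and at 213 ± 21.9 and 303 ± 22.2 CPM in experiment 2. The HOG1-KO basal libraries held 1 count of HOG1 in total against 8751 in WT, a depth-scaled ratio of 8855 with a 95% counting interval from 1589 to 349800. The HOG1-KO salt libraries held 0 counts against 12353, a ratio of 4460 against a floor of 3 counts over the group. The lower end of the 95% counting interval was 3627. Differences between the strains in basal cells did not pass the test for YLR112W (-0.05 ± 0.25 on the log2 scale) or AVL9 (0.16 ± 0.14), with edgeR adjusted p = 0.966 and 0.717. Salt raised HOG1 in experiment 1 (0.45 ± 0.10, adjusted p = 0.00128), and its change in experiment 2 WT cells did not pass the test (0.36 ± 0.18, adjusted p = 0.0994). That change passed with total counts alone as the scaling (adjusted p = 0.0181), without WT salt replicate 2 (0.0354) and without both WT libraries that deviated from their groups (0.0170), the last chosen after seeing the data.

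Transcripts of LEU2, MET17 and URA3, which BY4741 lacks, separated the experiments. LEU2 stood at 178 ± 9.85 CPM basal (SD, n = 3) and 190.1 ± 0.710 CPM in salt in experiment 1, MET17 at 472 ± 23.8 and 214 ± 22.7 CPM, and URA3 at 25.8 ± 9.56 and 16.3 ± 3.14 CPM. No library of experiment 2 held more than 2 counts of any of these genes. HIS3, partly deleted in BY4741, was at 906 ± 41.2 CPM in basal WT cells of experiment 1 and at 70.3 ± 7.79 CPM in those of experiment 2. Library kit and marker transcripts thus differ together between the experiments, and levels were scaled within each experiment.

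**Figure D1:**
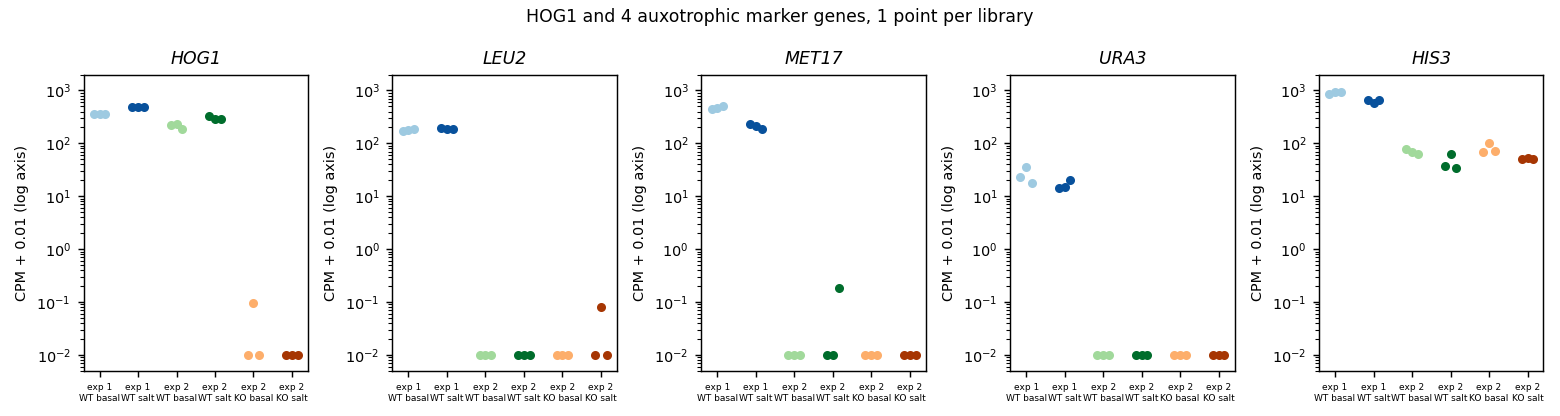
CPM of HOG1 and of the marker genes LEU2, MET17, URA3 and HIS3 in each library, with 0.01 added on a log axis; each point is 1 of 3 libraries per group. HOG1 is at 0 or 1 count in total in the HOG1-KO groups, and LEU2, MET17 and URA3 are at 2 counts or fewer in each library of experiment 2.

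In experiment 1, salt raised genes of glycerol production, trehalose metabolism and stress protection in WT cells and lowered genes of ribosome production. STL1, the glycerol importer of the plasma membrane, rose from 1.37 ± 0.509 to 6325 ± 676 CPM (SD, n = 3), a log2 change of 12.15 ± 0.25 (edgeR adjusted p = 3.27e-12). The glycerol synthesis enzymes GPD1 and GPP2 rose by 6.28 ± 0.18 and 6.29 ± 0.14 on the log2 scale, and the sodium pump ENA1 by 5.01 ± 0.11. Other large increases were RTC3 (8.93), FMP48 (8.80), the transketolase TKL2 (8.57), the aldehyde dehydrogenase ALD3 (8.42), the catalase CTT1 (8.16), the hexose transporter HXT5 (7.81), DDR2 (7.57), FMP45 (7.45) and HSP12 (7.41). The largest decreases by the rule for named genes were SYO1 (-6.10), UTP23 (-5.58), NOG2 (-5.57), RRP12 (-5.45), TRM11 (-5.34), MRD1 (-5.00), RFU1 (-4.91), NOG1 (-4.84), the CTP synthase URA7 (-4.73) and RRS1 (-4.72). The change of actin (ACT1) did not pass the test (-0.05 ± 0.15, adjusted p = 0.769).

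Of 25 tested osmostress genes with reported Hog1 dependence, 25 rose in experiment 1 (25 adjusted over the list alone), with a median log2 change of 5.60. Of 11 glycerol synthesis and transport genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 7.32e-04, adjusted p = 0.271 with an estimated correlation). Camera gave an adjusted p of 4.77e-15 for the osmostress list, and adjusted p = 0.148 with an estimated correlation. Of 34 general stress genes of the Msn2 and Msn4 type, 33 rose (33 adjusted over the list alone), and of 18 trehalose and glycogen genes 18 rose (18 adjusted over the list alone), among them TPS2 (6.01), PGM2 (5.81) and TSL1 (5.43). Their camera adjusted p-values were 4.14e-17 and 2.56e-10, each with adjusted p = 0.148 with an estimated correlation. Of 82 ribosome biogenesis genes 82 fell (82 adjusted over the list alone), by a median of -3.31, with the nucleolar protein gene NSR1 at -4.65 ± 0.12. Of 137 cytosolic ribosomal protein genes, 134 fell and 1 rose (135 and 1 adjusted over the list alone), by a median of -1.13. Camera adjusted p-values were 9.01e-27 and 1.40e-21, and adjusted p = 0.148 and 0.405 with an estimated correlation. RNA polymerase I and III subunits fell in 23 of 26 cases (23 adjusted over the list alone, camera adjusted p = 9.07e-09, adjusted p = 0.148 with an estimated correlation). Of 24 mating pathway genes, 11 rose and 5 fell (11 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.180). Over 5878 genes, 2082 were higher and 1987 lower in salt, of which 921 and 844 changed at least 2-fold.

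The WT response was measured again in experiment 2. STL1 rose by 11.32 ± 0.51 on the log2 scale (edgeR adjusted p = 8.54e-11, n = 3), HSP12 by 9.74 ± 0.33, RTC3 by 9.45 ± 0.34, CTT1 by 8.06 ± 0.23, GPD1 by 6.93 ± 0.27 and GPP2 by 6.88 ± 0.20. FMP48 (9.22), TKL2 (8.85), DDR2 (8.47), ALD3 (8.02), HXT5 (7.97) and NQM1 (7.60) were also among the largest increases. The phosphate transporter PHO84 had the largest decrease (-5.89 ± 0.48), followed by NOG1 (-4.60), the purine salvage enzyme HPT1 (-4.51), SYO1 (-4.49), RRS1 (-4.35), NOG2 (-4.32), RRP12 (-4.29), GFD2 (-4.21), NSR1 (-4.17) and BSC1 (-4.03). Osmostress genes rose in 24 of 25 cases (24 adjusted over the list alone), general stress genes in 34 of 34 (34 adjusted over the list alone), and stationary phase genes in 15 of 18 with 1 lower (15 and 1 adjusted over the list alone). Camera called these 3 lists also with an estimated correlation (adjusted p = 0.00939 each). Ribosome biogenesis genes fell in 81 of 82 cases (81 adjusted over the list alone, camera adjusted p = 8.77e-33, adjusted p = 0.0935 with an estimated correlation). Among 6107 genes, 1836 were higher and 1659 lower. Across the 5804 genes tested in both experiments, log2 changes correlated at r = 0.93 and rho = 0.90, where genes are not independent replicates. In both experiments 1506 genes were higher, against 621 for independent lists, 1433 were lower, against 556, and 21 were called in opposite directions.

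**Figure D2:**
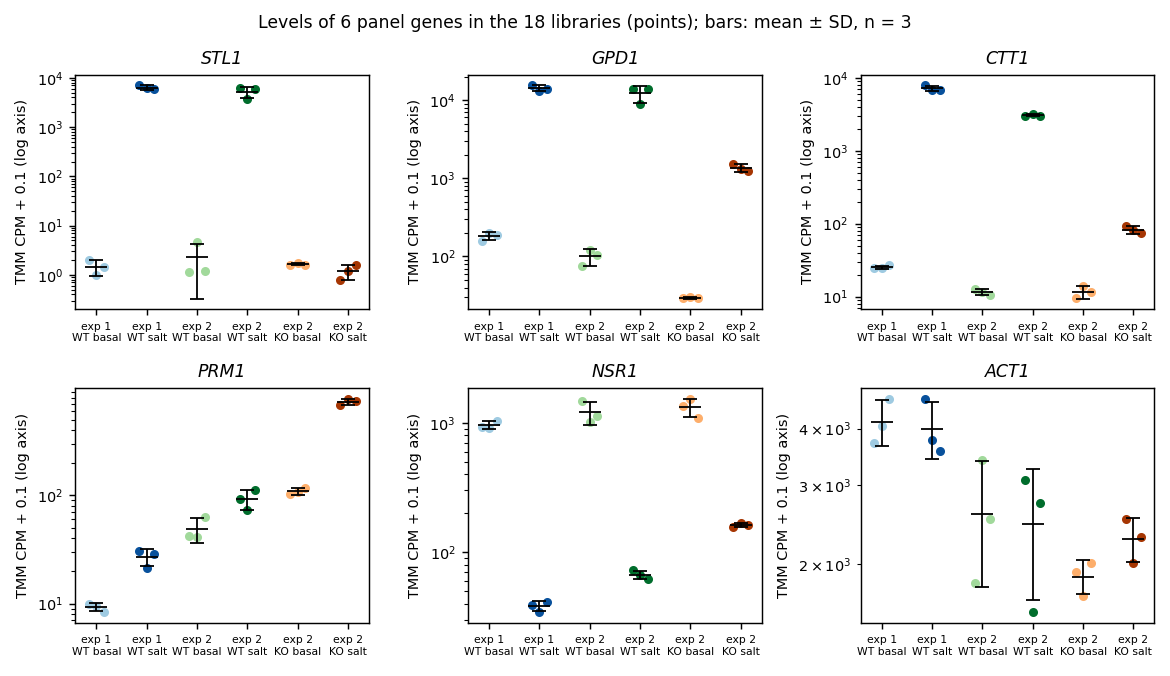
TMM-scaled CPM, with 0.1 added on a log axis, of STL1, GPD1, CTT1, PRM1, NSR1 and ACT1 in each library (points), with mean and SD over 3 libraries per group, scaled within each experiment. STL1 is at 5190 ± 1329 CPM in salt-treated WT cells of experiment 2 and at 1.07 ± 0.392 CPM in salt-treated HOG1-KO cells.

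In experiment 2, WT basal replicate 1 and WT salt replicate 2 stood apart from the other libraries of their groups. Their deviations from the group means correlated across 5665 genes at r = 0.80, where genes are not independent replicates. Both were lower for glycolysis (median log2 deviations of -0.44 and -0.61), cell wall integrity (-0.41 and -0.51), ergosterol synthesis (-0.38 and -0.50) and hexose transporters (-0.30 and -0.69), and higher for ribosome biogenesis (0.19 and 0.32). Without these libraries, a choice made after seeing the data and because they deviated, 2005 genes were higher and 1948 lower in salt-treated WT cells. Without WT salt replicate 2 alone these counts were 1703 and 1942, and with total counts alone as the scaling 2008 and 1234. Scaling by total counts alone moved the median log2 change of all genes from 0.04 to 0.21 in WT, to 0.19 in HOG1-KO, to 0.17 for the strains in basal cells, to 0.16 for the strains in salt and to 0.22 for the difference between experiments, and changes are given relative to the TMM scale.

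HOG1-KO cells also responded to salt. The change of STL1 did not pass the test there, at 1.56 ± 0.0837 CPM basal and 1.07 ± 0.392 CPM in salt (log2 change -0.51 ± 0.51, edgeR adjusted p = 0.412, n = 3). The galactose permease gene GAL2 rose by 6.87 ± 0.37 on the log2 scale (adjusted p = 2.64e-09), PHM8 by 6.82 ± 0.32 and IRC15 by 6.14 ± 0.38, followed by HSP12 (5.82), RTC3 (5.78), GPD1 (5.52), the small heat shock protein HSP42 (5.05), ROQ1 (5.02), DDR2 (5.02) and TPO4 (4.92). GRE2 and SIP18 did not pass the test (-0.28 ± 0.20 and -0.44 ± 0.34, adjusted p = 0.250 and 0.282), and the hexose transporter HXT1 fell (-0.93 ± 0.27, adjusted p = 0.00902). PHO84 (-5.11), HPT1 (-3.82), PRM7 (-3.80), BSC1 (-3.61), SYO1 (-3.38), RRS1 (-3.13), the malic enzyme MAE1 (-3.05), NSR1 (-3.02), CGR1 (-2.87) and NOG1 (-2.86) had the largest decreases. Osmostress genes rose in 18 of 25 cases with 1 lower (19 and 1 adjusted over the list alone), and general stress genes in 31 of 34 (32 adjusted over the list alone), with camera adjusted p = 5.98e-08 and 1.47e-15 and adjusted p = 0.0558 and 0.0522 with an estimated correlation. Of 26 mating pathway genes, 21 rose and 1 fell (22 and 1 adjusted over the list alone), among them PRM4 (3.46), PRM1 (2.76), FUS2 (2.75) and FUS1 (2.73), which act in mating. Camera gave an adjusted p of 2.26e-08 for this list, and adjusted p = 0.0932 with an estimated correlation. Of 11 glycerol genes 5 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.243), and their median of 0.05 became -0.04 with GC and length offsets.

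Ribosome biogenesis genes fell in 79 of 82 cases in HOG1-KO cells (81 adjusted over the list alone, camera adjusted p = 3.83e-29, adjusted p = 0.0973 with an estimated correlation). The phosphate regulon, with 2 genes higher and 9 lower among 16 (2 and 9 adjusted over the list alone), had a camera adjusted p of 0.0596, and 0.0343 with the replicate number as a block. Without the block it had adjusted p = 0.743 with an estimated correlation. In total 1756 genes were higher and 1562 lower, and with total counts alone as the scaling 1980 and 1053. Without the deviating WT libraries, which share the estimate of spread, 2178 were higher and 2074 lower.

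**Figure D3:**
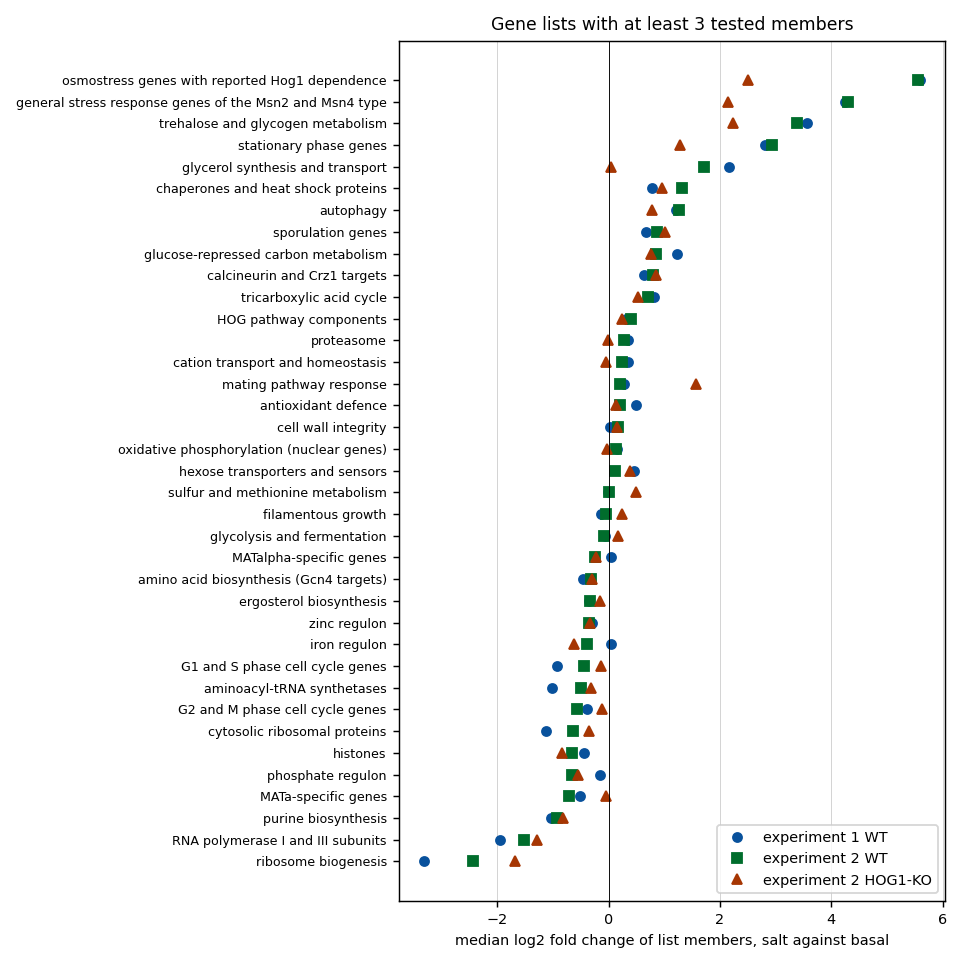
Median log2 fold change, salt against basal, of each gene list with at least 3 tested members, for WT in experiment 1, WT in experiment 2 and HOG1-KO in experiment 2. The osmostress list has medians of 5.60, 5.55 and 2.50, ribosome biogenesis -3.31, -2.43 and -1.68, and the mating pathway 0.27, 0.21 and 1.57.

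The difference between the strains' salt responses was tested directly. It is signed, so for a gene that fell in both strains a higher response is a smaller fall. The response was lower in HOG1-KO cells for STL1 (-11.83 ± 0.71 on the log2 scale, HOG1-KO minus WT, edgeR adjusted p = 2.14e-08, n = 3), ALD3 (-6.22 ± 0.26), HBT1 (-5.83), PRM10 (-5.52), FMP48 (-5.49), NQM1 (-5.49), CTT1 (-5.22 ± 0.26), FMP45 (-5.20), GRE2 (-4.72) and PHM7 (-4.46), and among glycerol enzymes for GPP2 (-2.95 ± 0.23) and GPP1 (-2.69 ± 0.22). It was higher for the mating genes PRM6 (4.24 ± 0.33), PRM4 (2.32) and FAR1 (2.15), for RSB1 (3.28), SFG1 (3.02), AQR1 (2.52), the cyclin PCL2 (2.38), GAL2 (2.37) and NOG2 (2.08). Osmostress genes had a lower response in 21 of 25 cases (21 adjusted over the list alone), general stress genes in 22 of 34 (25 adjusted over the list alone), trehalose and glycogen genes in 13 of 18 (16 adjusted over the list alone) and stationary phase genes in 8 of 18 (9 adjusted over the list alone). Camera called these lists also with an estimated correlation (adjusted p = 8.74e-04, 0.00416, 0.0466 and 0.00461). The deviating WT libraries had median log2 deviations of -0.20 and -0.33 for the trehalose and glycogen list and 0.10 and 0.20 for the stationary phase list. Without both libraries the median differences of these lists went from -1.37 to -1.40 and from -0.88 to -1.09. Mating pathway genes had a higher response in 19 of 26 cases and a lower one in 3 (20 and 4 adjusted over the list alone), also with an estimated correlation (adjusted p = 0.0466). Ribosome biogenesis genes, higher in the deviating WT libraries by a median of 0.19 and 0.32, had a higher response in 38 of 82 cases (53 adjusted over the list alone, camera adjusted p = 3.61e-23, adjusted p = 0.179 with an estimated correlation). The median log2 change of this list was -2.43 in WT and -1.68 in HOG1-KO, a smaller fall in HOG1-KO. Over 6107 genes, 279 responses were higher and 320 lower in HOG1-KO. With the replicate number as a block the numbers were 148 and 212. Every library correlated best with its own number in HOG1-KO and not in WT. Without WT salt replicate 2 the number higher was 589, and without both deviating libraries the numbers were 611 and 637, with 589 of the 599 genes shared.

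**Figure D4:**
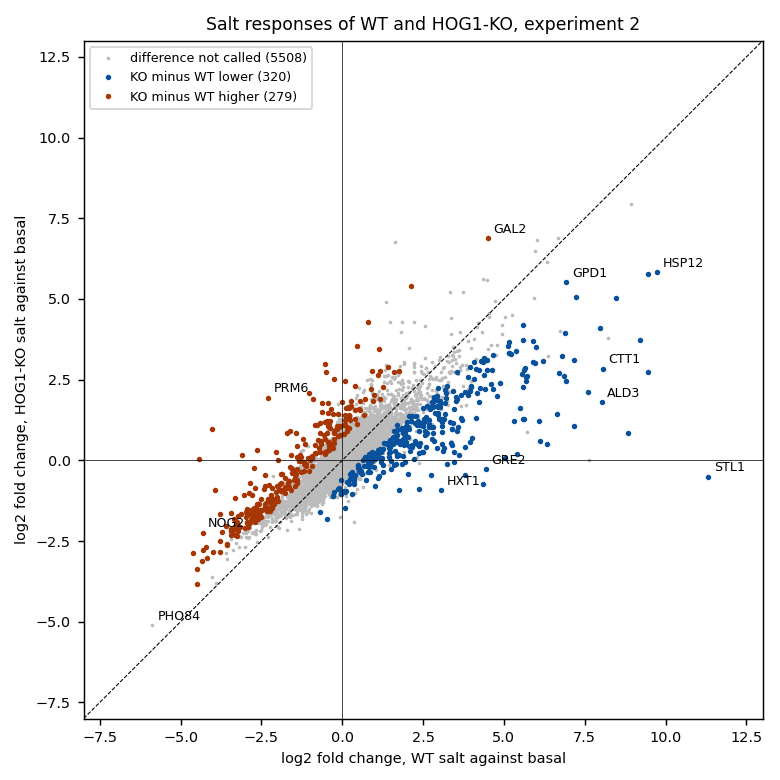
Log2 fold change in salt of each of 6107 genes in WT (x axis) and HOG1-KO cells (y axis) of experiment 2; coloured points are the 279 and 320 genes whose response was called higher or lower in HOG1-KO, and the dashed line marks equal responses. STL1 lies at 11.32 in WT and -0.51 in HOG1-KO, and PHO84 at -5.89 and -5.11.

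The responses of the strains correlated across genes at r = 0.84 and rho = 0.86, where genes are not independent replicates, and the SD of the HOG1-KO changes was 0.767 times that of WT. Higher in both were 1367 genes, against 528 for independent lists, and lower in both were 1261, against 424. A further 11 genes rose in WT and fell in HOG1-KO with a called difference, among them HXT1 (3.06 and -0.93), the glycerol phosphatase GPP1 (1.76 and -0.93) and the cell wall protein gene FIT1 (2.37 and -0.87). Another 19 fell in WT and rose in HOG1-KO, among them PRM6 (-2.30 and 1.94), the agglutinin subunit AGA1 (-0.85 and 1.10), the transcription factor TEC1 (-0.44 and 1.47) and the cyclin CLB1 (-1.39 and 0.44). Those that rose in WT and fell in HOG1-KO numbered 5 without HOG1-KO basal replicate 1, 7 without HOG1-KO salt replicate 1, 7 without HOG1-KO salt replicate 3 and 6 with total counts alone as the scaling. Those that fell in WT and rose in HOG1-KO numbered 33 without WT salt replicate 2 and 12 without HOG1-KO salt replicate 3, and without both deviating libraries each class held 40 genes. With the replicate number as a block the classes held 7 and 11. The examples named were chosen after their values were seen. Without WT basal replicate 3 the WT decrease of AGA1 did not pass the test (edgeR adjusted p = 0.0654), nor did it with only the 6 libraries compared (0.0627). The WT decrease of TEC1 ended without WT basal replicates 1 or 3 or WT salt replicates 1 or 3 (edgeR adjusted p = 0.0825, 0.0669, 0.0960 and 0.0707), with only the 6 libraries compared (0.0714) and with total counts alone as the scaling (0.280). In HOG1-KO cells the increase of CLB1 ended with the replicate number as a block (0.0677) and without basal replicates 2 or 3 or salt replicates 2 or 3 (0.0539, 0.0606, 0.0850 and 0.0603, edgeR adjusted p). The HOG1-KO decrease of FIT1 ended without basal replicate 1 or salt replicate 3 (edgeR adjusted p = 0.0607 and 0.0508), while the called difference between the strains held for all 7 examples under the alternatives run.

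Genes changed at least 2-fold in experiment 1 were then followed in experiment 2, whose libraries played no part in choosing them. Of 901 such genes that rose, the median log2 change in experiment 2 was 1.76 in WT and 1.18 in HOG1-KO, a median difference of -0.56 (95% bootstrap interval -0.60 to -0.53, which resamples genes and leaves out the spread between libraries). The response was smaller in HOG1-KO for 267 of them and larger for 7 (348 and 10 adjusted over the list alone), and 725 were called in HOG1-KO cells. Of 837 genes that fell, the medians were -1.40 and -1.06, the median difference was 0.39 (0.37 to 0.42), 165 responses were smaller and 1 was larger (210 and 1 adjusted over the list alone). Without WT salt replicate 2 the median differences were -0.50 for genes that rose and 0.53 for genes that fell, both outside these intervals. The smaller responses among genes that fell then numbered 319, and the larger ones among genes that rose 11. The latter numbered 4 without WT salt replicate 3 and 4 without HOG1-KO salt replicate 2, and without WT basal replicate 1 the larger responses among genes that fell numbered 2. Without both deviating libraries the smaller responses numbered 409 and 326, and the larger ones 13 and 6. With the replicate number as a block the smaller responses numbered 196 and 89, and the larger ones 4 and 1.

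In basal cells, genes of the cell wall and of mating were among those called between the strains. The cell wall protein gene CWP1 was lower in HOG1-KO, at 10.2 ± 2.89 against 191 ± 62.9 CPM (SD, n = 3; log2 difference -4.22 ± 0.34, edgeR adjusted p = 4.69e-06), as were the cell wall protein gene SED1 (-2.55 ± 0.29), PNS1 (-2.04), HXT1 (-2.01 ± 0.27), YRO2 (-1.90), GPD1 (-1.76 ± 0.22), YGP1 (-1.64) and GPP2 (-1.10 ± 0.17). The pectinase gene PGU1 was higher, at 19.5 ± 3.77 against 1.62 ± 0.301 CPM (3.61 ± 0.24, adjusted p = 3.26e-07), and ASG7 was higher by 0.93 ± 0.14. The mating genes PRM6 (1.22 ± 0.21), PRM1 (1.14 ± 0.19) and FUS1 (0.75 ± 0.13) and the receptor gene STE3 (1.33 ± 0.24) were higher with edgeR adjusted p from 0.00852 to 0.0105. Without WT basal replicate 2 these 4 calls ended (adjusted p = 0.0749, 0.0749, 0.0629 and 0.0780), as did those of PRM6 and STE3 without HOG1-KO basal replicate 3 (0.0708 and 0.0730) and that of FUS1 without HOG1-KO basal replicate 2 (0.0549). Of 26 mating pathway genes, 7 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 3.02e-10, adjusted p = 0.0842 with an estimated correlation). Of 24 cell wall integrity genes, whose median deviation was -0.41 in the deviating WT basal replicate 1, 2 were lower (5 adjusted over the list alone, camera adjusted p = 1.45e-05, adjusted p = 0.393 with an estimated correlation). The median difference of this list went from -0.35 to -0.53 without both deviating libraries.

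Of 6107 genes in basal cells, 29 were higher and 31 lower in HOG1-KO by edgeR, HOG1 included, while 655 had an unadjusted p under 0.05. With total counts alone as the scaling 42 were higher and 29 lower, and DESeq2 called 64 and 71. Without both deviating WT libraries 352 were higher and 701 lower. Without WT basal replicate 2 the counts were 8 and 15, and without WT basal replicate 3 19 and 19. Without HOG1-KO basal replicates 1, 2 and 3 they were 19 and 20, 15 and 14, and 14 and 18.

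In salt, more genes were called between the strains than in basal cells. HOG1-KO cells had more PRM6 (5.45 ± 0.26 on the log2 scale, edgeR adjusted p = 4.88e-10, n = 3), SFG1 (3.48), PRM1 (2.99), FIG1 (2.96), the aquaporin AQY2 (2.84), PRM4 (2.83), TEC1 (2.64), FIG2 (2.62), AQR1 (2.59) and FAR1 (2.51) than WT. They had less STL1 (-12.21 ± 0.53), TKL2 (-8.92), PRM10 (-7.01), ALD3 (-6.50), CWP1 (-6.29), HXT1 (-5.99), GRE2 (-5.76), MPC3 (-5.33) and HBT1 (-5.27), and less of the glycerol enzymes GPP2 (-4.05 ± 0.17), GPP1 (-3.34 ± 0.17) and GPD1 (-3.17 ± 0.23). Osmostress genes were lower in 23 of 25 cases (24 adjusted over the list alone) and general stress genes in 29 of 34 (31 adjusted over the list alone), also with an estimated correlation (camera adjusted p = 0.00170 and 0.00483). Mating pathway genes were higher in 21 of 26 cases and lower in 3 (21 and 3 adjusted over the list alone), also with an estimated correlation (adjusted p = 0.0333). Of 82 ribosome biogenesis genes, 63 were higher (67 adjusted over the list alone, camera adjusted p = 3.07e-24, adjusted p = 0.163 with an estimated correlation). This list had a median deviation of 0.32 in WT salt replicate 2, and its median difference of 0.93 was 1.07 without both deviating libraries. In total 783 genes were higher and 759 lower, and with total counts alone as the scaling 997 and 447. Without WT salt replicate 2 the number higher was 1200, and without both deviating libraries the numbers were 1487 and 1437.

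The WT responses of the experiments were also compared, although kit and marker transcripts differ between them. The difference is signed, so for a gene that fell in both experiments a higher response is a smaller fall and a lower one a larger fall. Ribosome biogenesis genes fell in both, by medians of -3.31 in experiment 1 and -2.43 in experiment 2. The response of PHO84 was lower in experiment 2 (-4.36 ± 0.46 on the log2 scale, edgeR adjusted p = 2.44e-04, n = 3), as was that of SPL2 (-3.01 ± 0.40), both of the phosphate regulon. Basal PHO84 was at 10.3 ± 0.998 CPM in experiment 1 and 386 ± 177 CPM in experiment 2, each scaled within its experiment. The responses of TRM11 (2.71 ± 0.28), HSP12 (2.28 ± 0.31), PHM8 (2.25), URA7 (2.23 ± 0.19), ENP2 (2.22), DRS1 (1.96) and RTS3 (1.89) were higher in experiment 2. Basal WT libraries held HSP12 at 25.5 to 27.5 CPM in experiment 1 and at 1.23 to 2.29 CPM in experiment 2. WT salt libraries held it at 4336 to 4685 and at 1155 to 1688 CPM, each scaled within its experiment. Of 82 ribosome biogenesis genes 18 were higher (34 adjusted over the list alone), of 30 chaperones and heat shock proteins 6 (11 adjusted over the list alone), and of 16 phosphate regulon genes 3 were lower (8 lower and 1 higher adjusted over the list alone). Camera adjusted p-values were 3.35e-14, 1.13e-08 and 1.64e-05, and adjusted p = 0.573, 0.399 and 0.399 with an estimated correlation. In the deviating WT basal replicate 1 and salt replicate 2 the median deviations were 0.19 and 0.32 for ribosome biogenesis, 0.04 and 0.29 for chaperones and -0.29 and -0.13 for the phosphate regulon. Without these libraries the median difference went from 0.55 to 0.58 for ribosome biogenesis, from 0.59 to 0.54 for chaperones and from -0.61 to -0.59 for the phosphate regulon.

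In total 93 responses were higher and 64 lower in experiment 2, with total counts alone 98 and 24, and with GC and length offsets, added after seeing the data, 193 and 72. DESeq2 called 239 and 157, and without both deviating libraries the counts were 455 and 359. With the replicate number as a block they were 13 and 4, and 32 and 7 with GC and length offsets as well. In neither experiment did every WT library correlate best with its own number. Without experiment 1 basal replicates 1, 2 and 3 the counts were 51 and 13, 49 and 24, and 72 and 36. Without experiment 1 salt replicates 1, 2 and 3 they were 51 and 33, 53 and 40, and 62 and 29. Without experiment 2 basal replicates 1, 2 and 3 they were 175 and 164, 55 and 36, and 51 and 35, and without experiment 2 salt replicate 2 the number lower was 111.

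Upstream sequences were compared between classes of experiment 1 genes. Genes that rose at least 2-fold more often carried the stress response element STRE, 64.2% of 854 against 28.0% of 1673 genes not called (Fisher's exact test, adjusted p = 4.33e-67), and a TATAWAW box, 53.4% against 39.0% (adjusted p = 4.04e-11). Genes that fell at least 2-fold more often carried the PAC core, 54.7% of 817 against 23.2% (adjusted p = 1.03e-52), and the RRPE core, 59.7% against 29.8% (adjusted p = 3.67e-45). They also held an intron more often, 9.91% against 3.88% (adjusted p = 5.06e-08), a difference that was -1.27 percentage points without the ribosomal lists and 0.125 with classes from experiment 2. The median upstream gap was 497.5 bp for genes that rose and 445.5 bp for genes that fell, against 391 bp for genes not called. Permutation tests gave adjusted p = 2.70e-05 and 0.00167. Median coding GC was 1.34 and 0.590 points above that of genes not called (permutation tests, adjusted p = 2.70e-05 and 0.00123). Basal levels were taken from the WT basal libraries of experiment 2. The median basal level differed from that of genes not called by -0.933 log2 units for genes that rose and by 1.82 for genes that fell, each with a permutation p of 1e-05, the smallest such a test can give (adjusted p = 2.70e-05). Among genes that rose and were tested for the difference between the strains, the 258 with a smaller response in HOG1-KO carried an STRE more often than the other 588, 76.4% against 58.8% (adjusted p = 3.73e-06), and a TATAWAW box in 59.7% against 50.7% (adjusted p = 0.0300). The 258 and 588 genes were not matched for the size of the WT response. Nor were they matched for the upstream gap, with medians of 568.5 and 480 bp (permutation test, adjusted p = 0.00989). A smaller response in HOG1-KO was called for 56.5% of genes that rose at least 4-fold in experiment 1, against 29.6% at 2-fold. Whether the STRE and TATAWAW shares go with Hog1 dependence or with the size of the response was not tested. Genes within a class are not independent replicates.

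**Figure D5:**
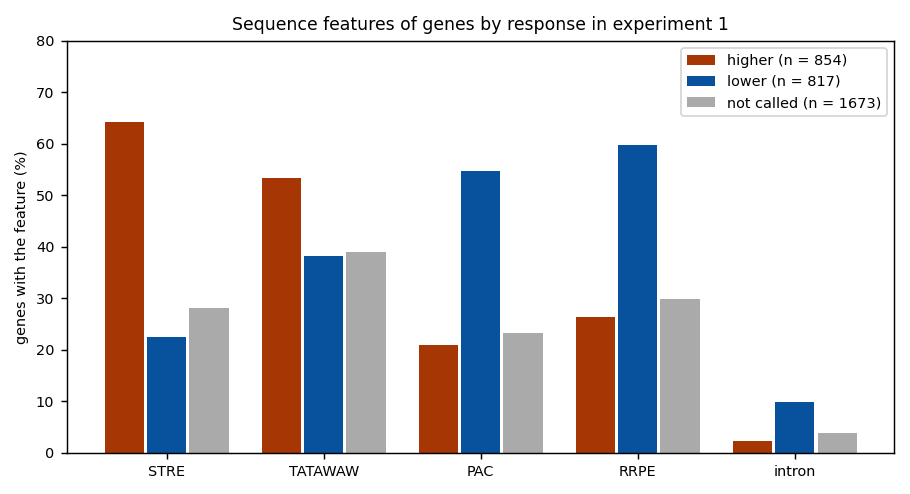
Share of genes (percent) with an STRE, TATAWAW box, PAC core, RRPE core or intron, for genes at least 2-fold higher (n = 854), at least 2-fold lower (n = 817) and not called (n = 1673) in salt-treated WT cells of experiment 1. An STRE is found in 64.2%, 22.5% and 28.0% of the classes.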

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

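The tests of exchanged labels, of reads carried over and of mixed cells were chosen only after the results they measure had been seen.

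The salt response differed between the strains by a test of the difference itself, with 279 responses higher and 320 lower in HOG1-KO. Of these genes, 11 rose in WT and fell in HOG1-KO, and 19 fell in WT and rose in HOG1-KO. Of 100 splits of the strain labels within each condition, 11 gave as many called genes, the real one included (599 real, 1155 the highest other), so this share does not exclude chance. All 10 other splits with as many genes moved basal libraries alone and kept the strain difference in salt, so they are no case without a difference. The 88 splits that moved salt libraries called 0 genes each by edgeR. They put salt libraries of both strains, which differed at 1542 genes, into 1 group. That widens the spread within groups, so these splits decide nothing either. For the 5 comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05, with 1 split as large in each, the highest other at 0, and real counts of 4069 and 3495 for the WT responses of experiments 1 and 2, 3318 for the HOG1-KO response, 60 for the strains in basal cells and 1542 in salt.

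The WT salt response differed between the experiments by the same kind of test, with 93 responses higher and 64 lower in experiment 2. With the replicate number as a block, 13 were higher and 4 lower. With the trends against coding GC and length removed 265 genes were called, which argues against those trends as the whole cause, and without the deviating libraries the median difference of the called genes, signed by the call, was 1.25 against 1.26 with them, which argues against these libraries as the cause. Of 100 splits of the experiment labels, 6 gave as many genes, the real one included, so this share does not exclude chance, and the highest other, which exchanged all salt libraries between experiments and so set their levels against each other, called 3515 against 157 and points to a structure of the samples. Each of the 5 others as large moved libraries of 1 condition alone and is no case without a difference. The 86 splits that moved both called 0 genes each by edgeR. They mixed libraries of both experiments within groups, which widens the spread, so they decide nothing either. Library kit, marker transcripts and experiment differ together, so effects that go with them cannot be told apart, and no biological explanation was tested.

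Transcripts of genes that the labelled BY4741 genotype lacks appeared in experiment 1, at a mean of 184 CPM for LEU2, 343 CPM for MET17 and 21.0 CPM for URA3. The highest count of these genes in a library of experiment 2 was 2, which argues against reads carried over from there. The lowest count of these genes in a library of experiment 1 was 168, which argues against cells of another strain in some of its cultures alone. Within groups the coefficient of variation of the 3 genes was 1.56 times that of genes of similar level with TMM scaling and 0.795 times with total counts alone, so it depended on the scaling and decides nothing. Such cells in all of its cultures and a strain with intact markers stay open, and neither these nor a biological explanation was tested.

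Experiment 2 WT basal replicate 1 and WT salt replicate 2 deviated together from their groups, by lower glycolysis, cell wall, ergosterol and hexose transporter genes and higher ribosome biogenesis genes. Their deviations correlated at 0.80 across genes, and at 0.759 with the trends against coding GC and length removed, which argues against those trends as the whole cause, although the deviations also ran with GC at rho of -0.41 and -0.30. Of the genes that rose at least 2-fold in experiment 1, 98.1% lay higher in salt replicate 2 than in basal replicate 1, which argues against exchanged labels. The groups of the design give no biological explanation for 1 library in each, and none was tested.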

How the results depend on the processing

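The fit without the deviating WT libraries, the offsets for GC and length and the thinned counts were chosen only after the data were seen. The numbers of genes given for each contrast are those higher and lower in turn, and for results that moved the cause was not tested unless the setting itself shows it.

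Leaving out 1 library in turn gave, as lowest and highest values, 1908 to 2147 higher and 1817 to 2043 lower for the experiment 1 response, 1625 to 1904 and 1507 to 1942 for the WT response in experiment 2, and 1492 to 1590 and 1282 to 1387 for the HOG1-KO response. For the difference between the strains' responses the ranges were 196 to 589 and 242 to 407, the upper end of the first without WT salt replicate 2. For the strains in basal cells they were 8 to 33 and 14 to 45, with the lowest 8 without WT basal replicate 2 and the lowest 14 without HOG1-KO basal replicate 2. For the strains in salt they were 552 to 1200 and 509 to 1007, and for the difference between experiments 49 to 175 and 13 to 164, the lowest without experiment 1 basal replicates 2 and 1 and the highest without experiment 2 WT basal replicate 1. For genes chosen in experiment 1, the smaller responses in HOG1-KO ranged 219 to 311 among genes that rose and 117 to 319 among genes that fell, and the larger ones 4 to 11 and 1 to 2. Genes called in opposite directions in the strains ranged from 5 to 13 for those higher in WT and lower in HOG1-KO and from 12 to 33 for the reverse with 1 library left out, and numbered 1 and 1 against a fold of 1.5, 40 and 40 without both deviating libraries, and 6 of the former with total counts alone.

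Against a fold of 1.5 (glmTreat) fewer genes passed, as its construction implies, with 1127 and 1051 for the experiment 1 response, 1035 and 821 for WT in experiment 2, 941 and 707 for HOG1-KO, 87 and 168 for the difference of responses, 2 and 11 for basal cells, 244 and 300 for salt and 22 and 8 for the difference between experiments. The call of HXT1 in HOG1-KO also ended there (edgeR adjusted p = 0.116), as did those of HOG1 in experiment 1, of AGA1 and TEC1 in WT of experiment 2, of FIT1 and CLB1 in HOG1-KO and of ASG7, GPP2, PRM1, PRM6, FUS1 and STE3 between the strains in basal cells (adjusted p from 0.155 to 1). DESeq2 called 64 and 71 genes for basal cells and 239 and 157 for the difference between experiments. With total counts alone as the scaling, 447 were lower in salt and 24 lower in the difference between experiments. Without both deviating libraries the counts were 611 and 637 for the difference of responses, 352 and 701 for basal cells, 1487 and 1437 for salt and 455 and 359 for the difference between experiments, of which 60 of the 60 basal genes and 157 of the 157 genes of the last were shared. GC and length offsets gave 193 higher in the difference between experiments. Among genes chosen in experiment 1, without both libraries the smaller responses numbered 409 and 326 and the larger ones 13 and 6. The larger responses numbered 1 and 0 for genes chosen at 4-fold, 18 and 2 at adjusted p alone, and 4 among genes that rose with total counts alone.

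Replicate numbers did not pair the WT basal and salt libraries, whose deviations correlated at -0.42, 0.03 and -0.35 in experiment 1 and -0.54, -0.52 and 0.50 in experiment 2, nor the strains, at -0.10, -0.06 and 0.01 in basal cells and 0.30, 0.10 and -0.20 in salt, and in none of these did every sample correlate best with its own number. With the replicate block the counts were 148 and 212 for the difference of responses and 13 and 4 for the difference between experiments, and 32 and 7 for the latter with GC and length offsets as well. Under the block, 7 genes were higher in WT and lower in HOG1-KO and 11 the reverse, 89 responses were smaller among genes that fell and 4 larger among genes that rose. For the HOG1-KO response, where every sample correlated best with its own number, the block gave 1548 and 1336 genes. It brought the phosphate regulon to a camera adjusted p of 0.0343 and ended the calls of AGA2 and ENO1 (edgeR adjusted p = 0.0655 and 0.0706). It changed no other call there of a list or of a gene named by the rule. Among the genes with opposite directions it ended HOG1-KO calls, that of CLB1 included (0.0677).

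Lists called higher and lower by camera numbered 13 and 8 in experiment 1, against 0 and 0 with an estimated correlation and 20 and 13 by fry. For WT in experiment 2 the estimated correlation gave 3 and 0 and fry 20 higher, for HOG1-KO 0 and 0 and fry 19 higher, for the difference of responses 1 and 4, for basal cells 0 and 0 and fry 3 and 5, for salt 1 and 3, and for the difference between experiments 0 and 0 and fry 2 and 1. The phosphate regulon in experiment 1, with a median of -0.15 and a mean of 0.36, turned from downward in camera to upward in fry (adjusted p = 0.00207), a test that does not compare the list with other genes.

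Among gene features, classes from experiment 2 were set against basal levels of experiment 1. For genes that rose they gave introns -2.18 percentage points and RRPE cores -5.01 points apart from genes not called. With classes from experiment 1 these were -1.54 and -3.48 points (Fisher's exact test, adjusted p = 0.0792 and 0.111). For genes that fell the upstream gap differed by 3 bp and introns by 0.125 points. The classes from experiment 1 gave 54.5 bp and 6.03 points. Genes with a smaller response in HOG1-KO had GC 1.42 points and basal level 0.522 log2 units higher than the other genes that rose. With classes from experiment 1 neither difference passed the permutation test, at 0.527 points of GC (adjusted p = 0.123) and 0.0207 log2 units of basal level. Without the ribosomal lists genes that fell differed by 0.403 points of GC, 34.5 bp of upstream gap and -1.27 points of introns, the last reversed in direction (adjusted p = 0.238), and fewer genes enter there. With those lists kept, the differences were 0.590 points, 54.5 bp and 6.03 points. Over the other results, values of named genes and of genes called in opposite directions were counted. Under settings other than leaving out 1 library, the fit without both deviating libraries included, 10090 held their side of the threshold, 508 lost it and 36 gained it. With 1 library left out 6326 held, 478 lost it and 6 gained it. With counts thinned at random to 50% in every library, fewer of the weaker transcripts are tested, and calls in the lowest of 3 equal classes of mean level numbered 982 against 1116 for the experiment 1 response, 104 against 133 for the difference of responses and 16 against 24 for the difference between experiments. In the highest class they numbered 1555 against 1579, 248 against 248 and 75 against 78. For the strains in basal cells the lowest and highest class gave 18 against 20 and 21 against 24.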

Other observations

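The gene groups named here come from lists fixed before the data were examined, while the scan for genes seen in 1 experiment alone was chosen only after the markers had been seen.

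Salt also moved groups outside stress protection and ribosome production in WT cells. In experiment 1, 21 of 23 glucose-repressed carbon metabolism genes rose (21 adjusted over the list alone), led by the hexokinase HXK1 (4.13 ± 0.15 on the log2 scale) and POT1 (2.89 ± 0.23). Of 24 autophagy genes 18 rose and 2 fell (18 and 2 adjusted over the list alone), with ATG8 at 3.11 ± 0.23. Of 36 proteasome genes 25 rose and 2 fell (25 and 2 adjusted over the list alone), with RPN4, the transcription factor of proteasome genes, at 1.43 ± 0.10. Of 15 purine synthesis genes 11 fell and 2 rose (11 and 2 adjusted over the list alone), with IMD4 at -2.15 ± 0.14. The camera adjusted p-values were 2.38e-05, 4.23e-04, 0.00334 and 0.00286, and adjusted p = 0.148, 0.148, 0.148 and 0.551 with an estimated correlation. In WT cells of experiment 2, 14 of 23 glucose-repressed genes rose with HXK1 at 4.49 ± 0.16 (1 fell, 14 and 1 adjusted over the list alone), and 17 of 24 autophagy genes rose with ATG8 at 2.95 ± 0.36 (1 fell, 18 and 1 adjusted over the list alone). The glucose-repressed list had median deviations of -0.06 and -0.37 in the deviating WT basal replicate 1 and salt replicate 2. Camera gave adjusted p-values of 0.00201 and 3.07e-05 there, and adjusted p = 0.244 and 0.0664 with an estimated correlation.

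In salt, HOG1-KO cells differed from WT in mating-type and cell cycle genes. Of 7 MATa-specific genes 6 were higher (7 adjusted over the list alone), with the receptor gene STE2 at 2198 ± 159 against 842 ± 229 CPM (SD, n = 3) and the pheromone gene MFA2 at 361 ± 45.6 against 132 ± 45.8 CPM. In the deviating WT salt replicate 2 this list had a median deviation of -0.50. Of 20 G2 and M phase genes 11 were higher (11 adjusted over the list alone), with the cyclins CLB2 at 1.73 ± 0.13 and CLB1 at 1.52 ± 0.15, and a median deviation of 0.21 in WT salt replicate 2. Of 10 histone genes 5 were lower (6 lower and 1 higher adjusted over the list alone), with HTA2 at -1.05 ± 0.17. Histone genes had a median deviation of 0.27 in WT salt replicate 2, and their median difference of -0.60 between the strains became -0.38 without the 2 deviating libraries, a choice made after seeing the data. The camera adjusted p-values were 2.07e-05, 3.55e-05 and 0.00922, and adjusted p = 0.212, 0.243 and 0.221 with an estimated correlation. STE3, a receptor gene of the other mating type, was at 17.1 ± 1.02 against 4.23 ± 1.23 CPM.

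A scan for genes with a mean of at least 20 CPM in 1 experiment and under 0.3 CPM in the other, with thresholds set after the data were seen, found LEU2, MET17 and URA3 in experiment 1 alone. In experiment 2 alone it found YFL032W (652 CPM), YGR025W (70.3 CPM), YLR366W (62.2 CPM), MIN10 (41.5 CPM) and YBR190W (38.4 CPM). Of these 5 features 2 stand in the reference annotation used here.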
